A study of Arabidopsis thaliana with 4 samples.

How the data were processed

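Chromatin of Arabidopsis thaliana seedlings (ecotype Col-0, a common laboratory strain) was immunoprecipitated with an antibody against histone H3 trimethylated on lysine 9 (H3K9me3) and compared with input chromatin on 2-colour tiling arrays. Per the labels' protocols, the seedlings were untreated and 10 days old, and were grown in liquid medium at 22 °C with 16 h of light. The labels describe 2 chromatin preparations, I and II. Each was hybridised as a dye-swap pair, with the immunoprecipitate in Cy5 on 1 array and in Cy3 on the other, so that 4 arrays form 1 group. Both labelled extracts were amplified, per the labels' protocols.

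The deposited table holds 1 signed score per array feature and array. What the authors did to make these scores is not given in the sources used here. The background correction, the normalization, the log base and the centring are therefore unknown. The deposited scores of the 2 arrays of a dye-swap pair were identical in all 21716 features that have a score, and the other 84 features were empty on all 4 arrays. The pair had thus been combined before deposit, the dye effect cannot be estimated, and each pair was counted as 1 replicate (n = 2 preparations). The medians of the 4 columns were -1.09 on both arrays of preparation I and -1.35 on both arrays of preparation II. The scores reach below 0, so they are not linear ratios. The direction of the score, immunoprecipitate over input or the reverse, is not stated either. The order of the samples in the titles is turned between the arrays of a pair while the scores are not, so the titles do not settle it. "Higher" and "lower" therefore refer to the score only. No value is given as a fold change.

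Of the 21800 features, 21761 have an identifier made of a plate number and a well, such as TB07H03, and are called tiles here. A score was given for 21716 tiles. The other 39 features (among them GFP, GUS and LUC) and 45 tiles have no score. None of the tile identifiers matched a gene identifier, symbol or accession in a gene table of the TAIR10.1 assembly. No gene name or genome position could therefore be attached to a tile. The comparisons planned by gene, by 8 gene lists fixed before the data were examined, by annotation class and by chromosome domain were not made. Spot brightness was not used here, so no tile could be filtered on weak signal. The number of preparations limits the precision.

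Each preparation was centred on the median of its 21716 tiles, with no further scaling, and the mean of both centred scores was tested against 0 with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). With 1 residual degree of freedom per tile, limma estimated an infinite prior number of degrees of freedom. All tiles then shared a spread of 0.200 score units per preparation (SD), and the test amounted to asking whether a mean score lay more than 0.31 from the median. The planned test of preparation I against II and the planned estimate of the dye effect could not be fitted, because the arrays within a pair do not differ. The labels do not say whether the preparations came from separate cultures. The p-values measure only the spread between these 2 preparations.

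A size count took tiles with a mean centred score of at least 1, or of -1 or less. Correlations between preparations, and between a tile and the next tile in identifier order (plate, then row A to H, then column 1 to 12), are across tiles, which are not independent replicates. The latter was set against 1000 shuffles of the tiles (numpy 2.4.6, scipy 1.17.1). The tiles named in the text follow a rule fixed before the data were examined: where identifiers carry no gene name, the 2 highest and the 2 lowest mean scores among tiles called by limma with the same sign on all arrays. Plates, the tiles of the longest run and the neighbours of the named tiles were named after their values were seen.

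The limma step was tested on simulated data, made of independent normal values with the spread that limma had estimated. Only 200 tiles were moved. Of 50 tiles moved by 1 score unit upwards, 100% were called, and of 50 moved downwards likewise 100%. For a move of 0.5 the share was 66% upwards and 48% downwards, and 11 of 21516 unmoved tiles were called. The simulation follows limma's own model, so it checks the computation only. In the real data 12276 tiles were called, which loosens the threshold, so these shares are not error rates of the real calls. The alternatives changed the centring, the scaling, the variance model, the threshold, the minimum size, the sign and the preparations used. A normal mixture with 2 components was fitted as another way of calling high tiles.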

Results

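H3K9me3 is a methylation mark on histone H3 that in animals marks condensed chromatin. In Arabidopsis it has been described mainly over genes, while H3K9me2 marks transposons. The series belongs to a reference map of chromatin marks in seedlings, and its comparison asks how strongly the mark is immunoprecipitated from each stretch of tiled sequence relative to input chromatin. The 4 arrays gave 2 distinct columns of scores, 1 for each chromatin preparation, over 21716 tiles. The deposited score of preparation I had a median of -1.09 and ran from -2.87 to 3.13. In preparation II the median was -1.35 and the range -3.25 to 3.14. All scores below are differences from the median of their own preparation, in score units. Which sign stands for more immunoprecipitated DNA is not stated in the sources used here, and the counts of higher and lower tiles trade places if the sign is turned.

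The scores had a narrow body and a long upper tail. The mean score was at least 1 above the median at 2585 tiles, 11.9% of those measured, and at least 1 below it at 71 tiles (0.327%). The lower count became 136 in preparation II alone, without preparation I, and 27 with the mode of each preparation as the zero. At a minimum size of 0.5 the counts were 5193 higher and 2432 lower. In preparation I the tile at the 99th percentile lay 2.14 above the median and the tile at the 1st percentile lay at -0.86. In preparation II these values were 1.82 and -0.94. The skewness was 1.05 in preparation I and 0.78 in preparation II. A mixture of 2 normal classes placed 36.8% of tiles in an upper class with a mean of 0.71 (SD 0.65 between tiles). The lower class had a mean of -0.18 (SD 0.32). No fit with 1 class was compared, so this share does not show that the tiles form 2 groups. At a posterior of 0.99 for the upper class 13.3% of tiles were called.

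**Figure D1:**
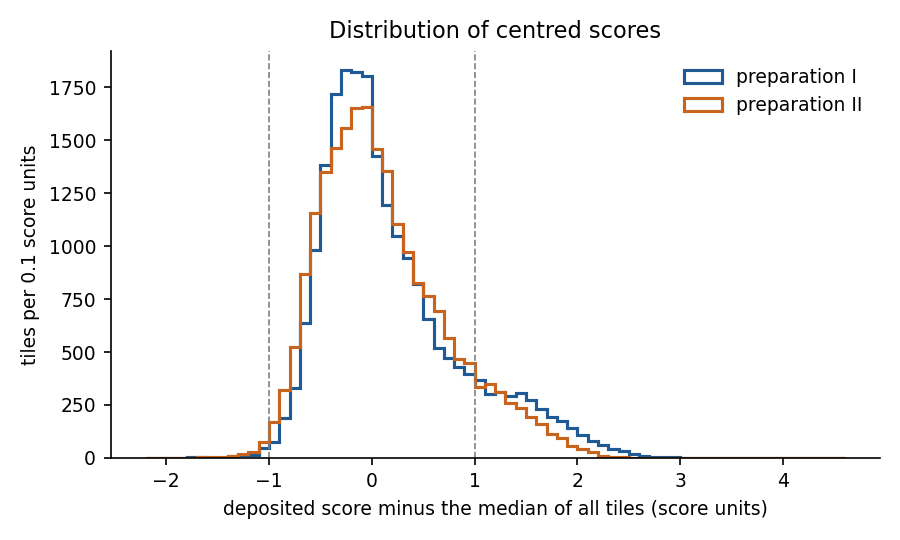
Number of tiles (vertical axis, per 0.1 score units) by centred score (horizontal axis, score units) in preparations I and II; dashed lines mark -1 and 1. Both distributions have a longer upper than lower tail, and 2585 tiles had a mean score of at least 1 against 71 at -1 or less (136 in preparation II alone, 27 with the mode as the zero).

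With limma, 6856 tiles scored higher than the median and 5420 lower (Benjamini-Hochberg adjusted p under 0.05, n = 2 preparations), so that 55.8% of the calls were higher. This split rests on the centring. With the mode of each preparation as the zero, which lay 0.20 below the median in I and 0.11 below it in II, 8078 tiles were higher and 2365 lower (77.4% higher). On the scores as deposited, with no centring, 664 were higher and 18246 lower (3.51% higher). When a tile had to exceed a difference of 0.5 by limma's treat test, 3227 tiles were higher and 235 lower.

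The highest score belonged to tile TB40E11, with a mean of 4.35 ± 0.19 (SD, n = 2). Tile TB40C07, on the same plate, followed with 3.59 ± 0.014 (SD, n = 2). The lowest tiles were TA06C05, at -1.78 ± 0.17 (SD, n = 2), and TA53H07, at -1.77 ± 0.027 (SD, n = 2). The standard error in the main limma fit was 0.14 for every tile, because all tiles shared 1 spread. All 4 tiles chosen by the rule, TB40E11, TB40C07, TA06C05 and TA53H07, passed the limma threshold under each setting tried. They were chosen as extremes among tiles already called on the same scores, so this gives no separate support. The largest of their adjusted p values in the main limma fit was 3.53e-34, for TA53H07. With a variance that may depend on the mean (limma trend, robust) the adjusted p of TB40E11 was 1.5e-13.

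The profile repeated between the preparations. Across the 21716 tiles Pearson's r was 0.92 and Spearman's rho 0.88. Within the 9287 tiles below the median of both preparations Pearson's r was 0.58, a value that the selection on both scores lowers by itself. Of the 3083 tiles at 1 or more in either preparation, 2059 (66.8%) were at 1 or more in both, where 297.8 would be shared by independent lists of the same sizes. At the lower end, 38 of 187 tiles (20.3%) were at -1 or less in both, against 0.557 for independent lists. The difference between preparations had an SD of 0.27 over all tiles, and exceeded 0.5 at 1563 tiles (7.2%). Preparation I had the longer upper tail: the 1086 tiles in the top 5% averaged 1.92 in I and 1.62 in II, a difference of 0.30 ± 0.27 (SD across tiles). Whether the preparations differ at a given tile could not be tested.

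**Figure D2:**
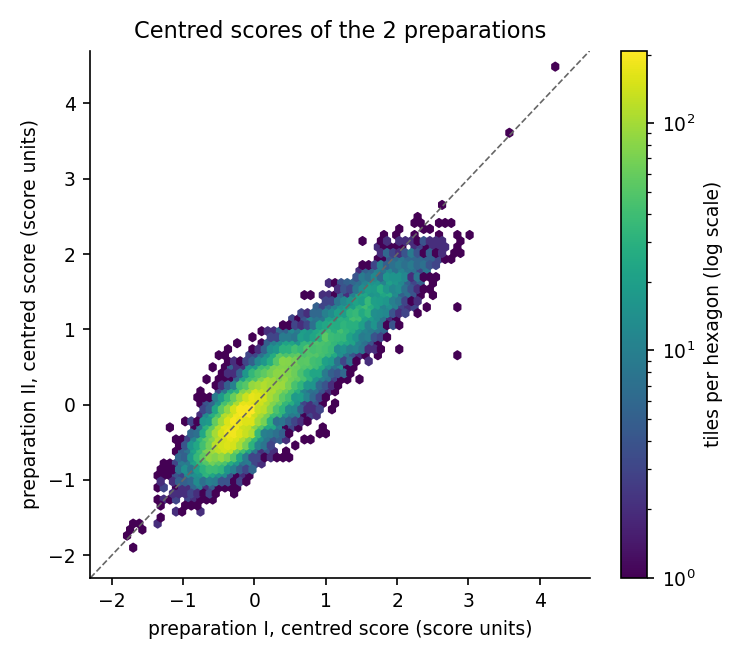
Centred score of each tile in preparation I (horizontal axis, score units) and preparation II (vertical axis, score units), coloured by the number of tiles per hexagon on a log scale; the dashed line marks equal scores. The points follow the line (Pearson's r 0.92 across tiles), and the tiles TB40E11 and TB40C07 stand apart at the top.

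Tiles with adjacent identifiers had like scores. The mean score of a tile correlated with that of the next tile with r = 0.68 across 21587 pairs (Spearman's rho 0.67), and the largest correlation in 1000 shuffled orders was 0.023. The correlation fell to 0.43 at a distance of 2 tiles, 0.30 at 3 tiles, 0.17 at 12 tiles and 0.11 at 96 tiles. It was 0.66 within preparation I alone and 0.67 within preparation II alone. Taking the wells of a plate by column in place of by row gave 0.17. With plate means subtracted the correlation was 0.60.

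**Figure D3:**
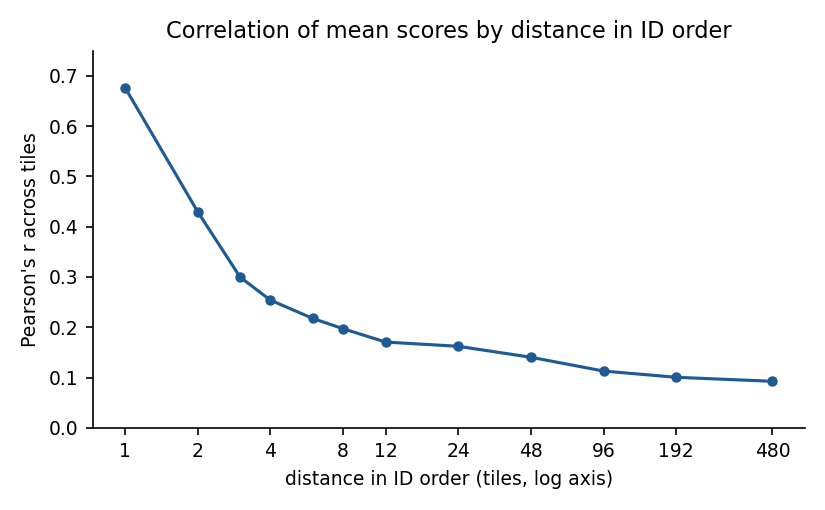
Pearson's r across tiles between the mean score of a tile and that of the tile a given distance later (horizontal axis, tiles in identifier order, log axis). The correlation falls from 0.68 at a distance of 1 tile to 0.43 at 2 tiles and 0.17 at 12 tiles.

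High tiles came in short stretches. The 2585 tiles at 1 or more formed 1254 runs of consecutive identifiers with a mean length of 2.06 tiles, while shuffled orders gave a mean length of 1.13 and at most 1.17. Single tiles made up 570 of the runs, and 369 runs held 2 tiles. Runs of 3 or more tiles held 49.4% of the high tiles, against 3.87% in shuffled orders. The longest run went from tile TB07H03 to tile TB08A10. Its 20 tiles averaged 1.74 ± 0.32 in preparation I and 1.58 ± 0.26 in preparation II (SD across tiles), and it crossed from plate TB07 into plate TB08. The longest run in any of 1000 shuffled orders was 7 tiles. The 71 low tiles also stood together more often than in shuffled orders. Their runs had a mean length of 1.203 tiles, against 1.003 in shuffled orders and at most 1.04, and 48 of them were in runs of 1 tile. The length of a tile in base pairs is not given in the sources used here, so these runs have no length in base pairs.

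**Figure D4:**
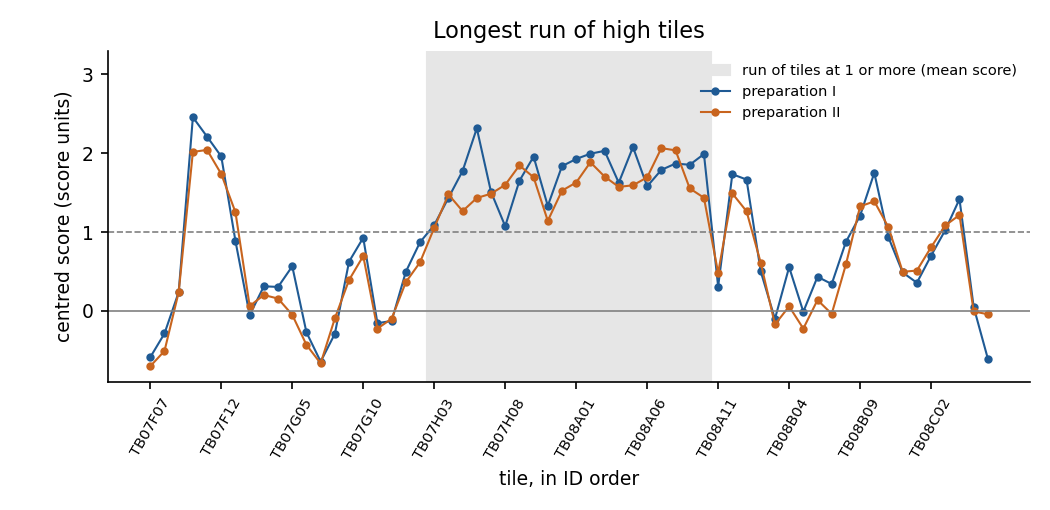
Centred scores (vertical axis, score units) of preparations I and II for the tiles from TB07H03 to TB08A10, shaded, and 20 tiles on either side, in identifier order (horizontal axis). The shaded tiles average 1.74 in preparation I and 1.58 in preparation II; the solid line marks the median of all tiles and the dashed line a score of 1.

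Plates differed in their typical score. Plate identity accounted for 19.1% of the variance of the mean score over 231 plates, and for at most 1.27% when the tiles were shuffled. Shuffling also removes the likeness of neighbouring tiles, so this contrast does not show that the plate itself is a source of variation. In the mean of both preparations the highest plate median was 0.634, on plate TB80, where 40.2% of the 82 measured tiles were at 1 or more. Plate TB54 was close, at 0.632, and was the highest in preparation II alone (0.58, against 0.48 on TB80). The lowest plate median in the mean of both was -0.68, on plate TC17, where none of the 60 measured tiles reached 1. Plate medians correlated between the preparations with Pearson's r = 0.95 across plates. On 27 plates no tile reached 1.

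**Figure D5:**
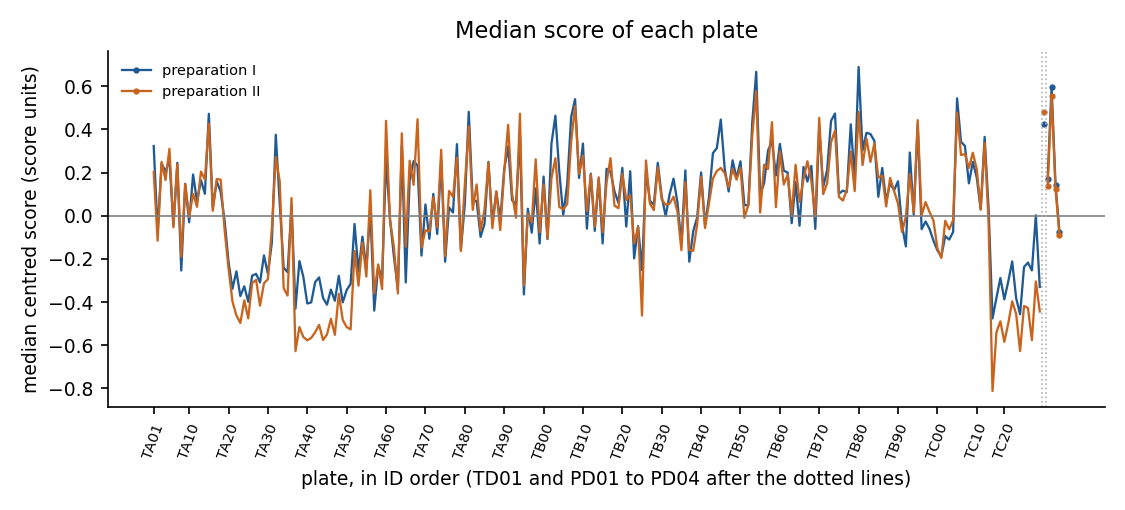
Median centred score (vertical axis, score units) of each plate in preparations I and II, in identifier order (horizontal axis). Plate medians of both preparations move together (Pearson's r 0.95 across plates). In the mean of both, the lowest is -0.68, on plate TC17, and the highest 0.634, on plate TB80, with TB54 at 0.632. In preparation II alone TB54 is the highest (0.58).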

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

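Tiles at 1 or more outnumbered those at -1 or less with median and mode centring and in each preparation alone, and turned signs reversed this. The counts of higher tiles by limma stayed within 1.5 times 6856 with mode centring, equal scaling, a mean-dependent variance and an adjusted p under 0.01. They moved to 664 without centring, to 3227 with the 0.5 minimum of the treat test, and to 2891 with the mixture model at a posterior of 0.99, by construction a narrower definition. Turned signs only exchange the 2 limma counts, to 5420 higher and 6856 lower. The counts of lower tiles moved from 5420 to 18246 without centring, 2365 with mode centring and 235 with the treat test. With a minimum size of 0.5 in place of 1, the counts were 5193 higher and 2432 lower. With mode centring, chosen after seeing the data, 27 tiles were at -1 or less. Turning all signs, also added later for the size counts, gave 71 higher and 2585 lower tiles, and turned the 4 named tiles to -4.35 (TB40E11), -3.59 (TB40C07), 1.78 (TA06C05) and 1.77 (TA53H07). Leaving out 1 preparation gave 2192 to 2950 higher tiles and 89 to 136 lower tiles against 71 in the mean of both, with 136 when preparation I was left out. The agreement of the preparations was 0.58 in tiles below both medians and 0.87 without the 5% of tiles at each end. The correlation of neighbouring tiles was 0.66 to 0.67 in a single preparation, 0.17 in column order and 0.60 with plate means subtracted. These settings were chosen after seeing the data. The other 24 values for the named tiles, which were chosen as extremes of the same scores, kept their direction and side of the threshold. The longest run of low plates, 15 plates, was 15 with a limit of 0.1, 4 with a limit of 0.3 and 12 with fully measured plates only. No limma test was possible with 1 preparation left out, since no residual degree of freedom remains. The settings that treat the 4 arrays separately, use 1 dye orientation or filter on dye-swap differences were not run, because the arrays of a pair hold the same scores.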

Other observations

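The tests below were chosen after the scores had been seen, except the one across plate boundaries, whose outcome was predicted before it was computed. Low scores were concentrated on certain plates. A plate was taken as low when its median lay more than 0.2 below that of all tiles in both preparations, and 36 of the 47 low plates fell into 4 runs of at least 3 consecutive plates. The longest run, plates TA37 to TA51, had a median score of -0.44 over 1352 tiles (-0.35 in preparation I and -0.53 in II), and 12 of these tiles (0.888%) were at 1 or more. Plates TA20 to TA28 had a median of -0.36 with 4.1% of tiles at 1 or more. Plates TC17 to TC25 had a median of -0.44 with 0.373%, and plates TA57 to TA59 a median of -0.34 with 1.39%. All other plates together had a median of 0.08 and 13.7% of tiles at 1 or more. The longest run of 15 plates compares with at most 7 in 1000 shuffles of the plates. With a limit of 0.3 it became 4 plates, and 13 of 26 low plates lay in runs. When only plates with 96 measured tiles were used it became 12 plates, and 20 of 32 low plates lay in 3 runs.

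The values argue against a uniform shift of whole plates as the whole cause of these low runs. Their 90th percentile lay at 0.11 against 1.197 on other plates, and their 10th percentile at -0.71 against -0.43. The upper end was lower by 0.81 more than the lower end (difference -0.81, 95% bootstrap interval over plates -0.93 to -0.69). The plates had been chosen by low medians of these same scores, and the interval does not allow for that choice. A part of the difference may therefore come from the choice. A shared shift as a part of the cause remains open, since the lower end was lower too. Weaker spots with compressed ratios remain open, since spot brightness was not used here. The 36 plates of the runs held 3248 measured tiles, fewer per plate than the other 195 plates with 18468. The preparations still correlated with r = 0.84 across tiles within the runs, against 0.91 on the other plates. The difference between preparations had an SD of 0.24 across tiles within the runs and 0.28 on the other plates. Compressed ratios could shrink this difference too, so these values do not decide it. A biological hypothesis is that these plates hold stretches of the tiled sequence whose level of the mark differs from the rest. They would be poor in the mark if the score is immunoprecipitate over input, and rich in it if the score is the reverse. Neither reading was tested here, since the direction of the score and the genome positions of the tiles are unknown.

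The likeness of neighbouring tiles is a second pattern. A shift shared by the tiles of a plate is excluded as the whole cause. The last well of a plate correlated with the first well of the next numbered plate with r = 0.62 over 222 boundaries, where the 97.5th percentile of shuffled plates was 0.13. Over 216 triples of plates the correlation was 0.59 with the next plate and 0.12 with the plate after next. The difference was 0.47 (95% bootstrap interval 0.30 to 0.64). Noise confined to 1 preparation was argued against as the whole cause by a correlation of 0.64 between a tile in 1 preparation and the next tile in the other. This value cannot speak to a technical pattern shared by the arrays of both preparations. Well position accounted for 0.453% of the variance, where shuffled tiles gave up to 0.668%. Identifiers numbered along the tiled sequence and a signal wider than a tile would give such values, but neither was tested. Sequence composition that changes slowly along the tiled sequence, overlap of adjacent tiles and DNA fragments longer than a tile were not tested either.

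Another pattern is small and follows plate numbers. Over 111 pairs of an even-numbered plate and the odd-numbered plate after it, the even plate had the higher median by 0.07 on average, in 73 of the pairs (two-sided sign-flip permutation p = 0.0012 from 100000 draws). The test was chosen after these same medians had been seen, so its p is not independent support. The difference between even and odd plates was 0.075 in preparation I and 0.075 in preparation II, with intervals over pairs that exclude 0 in both, so it did not come from 1 preparation. It was present at the 10th percentile of the plates (0.07, interval 0.04 to 0.09) and not detectable at the 90th (-0.01, interval -0.08 to 0.07). Plate medians correlated more with the second plate on (0.63) than with the next plate (0.54). A candidate source is the handling or printing of plates, which may add a part of this size to the differences between plates. The tiles of the low runs, with a median of -0.41, lie further from those of the other plates than this shift. Plates entered those runs by a limit on their median that is itself larger than this shift, so the greater distance follows from the choice. It cannot decide whether handling or printing contributed to the low runs.

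The highest tile stood alone. TB40E11 had a mean score of 4.35, while its neighbours TB40E10 and TB40E12 had 0.07 and -0.04. TB40C07, at 3.59, had 1.39 before it (TB40C06) and 0.10 after it (TB40C08). Of the lowest tiles, TA06C05 had neighbours at -1.48 (TA06C04) and -0.66 (TA06C06), and TA53H07 at -0.76 (TA53H06) and -0.74 (TA53H08).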
